A study of Mus musculus with 144 samples.

How the data were processed

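The series holds chromatin immunoprecipitation libraries of mouse marrow-derived mesenchymal stem cells kept undifferentiated, grown for 7 or 15 days in osteogenic medium (beta-glycerophosphate and ascorbic acid) or for 7 days in adipogenic medium (insulin, indomethacin and dexamethasone). Cells received vehicle or 100 nM 1,25(OH)2D3. Per the labels the exposure lasted 3 hours in the treatment protocol and 24 hours in the series design, and which holds could not be settled from the peak lists. Per the labels, differentiated cells were also washed with EDTA after fixation and homogenised to remove calcified matrix, a step not described for undifferentiated cells. Of 144 samples 140 have a peak list. The 4 input samples have none and are not analysed here. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

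Per the file headers, HOMER findPeaks was run on each library by itself at a false discovery rate of 0.001 and a genome size of 2e+09. Factor peaks were centred, of 178 to 389 bp, at least 356 to 778 bp apart, 4-fold over the input of the same state and over the local 10000 bp, at a Poisson p of 0.0001. Mark regions were built from windows of 1000 bp no more than 2500 bp apart, 4-fold over the local background, without input. Bowtie, HOMER and the mouse build mm9 are named in the submitters' processing notes, without versions. The deposited files give, as their only varying unit, other values, namely the start and end of each peak in base pairs. The deposited score column holds 1 in every line, so it carries no unit of peak strength. The total tags per library are those in the file headers, from 2463376 to 126432744 with a median of 38843448. The tags in peaks are printed there as a percent, under the name of approximate efficiency of the immunoprecipitation. Since reads carry no molecular identifiers, the intervals given cover counting error only, and the number of sites in them is not an independent count of molecules.

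Peaks on the mitochondrial chromosome were left out. Positions are 1-based on mm9. Genes came from GENCODE vM1 on the same assembly, 22225 of them protein-coding. Peak numbers per library were compared on the log2 scale with two-sided exact permutation tests, with treatment labels permuted within states or state labels within treatments. Benjamini-Hochberg adjustment was applied over the 5 marks, the other 9 antibodies or the 7 antibodies tested. The threshold was 0.05 throughout. Regions were merged over the libraries compared, with an overlap of 1 bp counted as held. A region was called gained when every library of the first group held it and no library of the second, and lost in the reverse case. Sites are regions held by both replicates of a group. Overlaps of sites were set against 100 circular shifts along each chromosome, and shares of sites have exact (Clopper-Pearson) 95% intervals. Gene lists were tested by the mean of regions gained minus lost within the gene body and 10 kb on each side. This mean was set against 10000 random lists matched for the number of regions near each gene, over 504 tests. Known elements were sought within 100 bp of each site's centre and in flanks 1 kb away, on both strands.

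The lists, fixed before the data were examined together with the comparisons and most alternatives, covered adipocyte, osteoblast, vitamin D target, mesenchymal progenitor, Wnt and TGF-beta signalling, glucocorticoid response and housekeeping genes. Markers of chondrocytes, muscle, haematopoietic cells, endothelium and neurons stood for other cell types the cultures could hold. Of 185 entries 184 matched a gene, 4 of them by an older symbol. Named genes followed a rule. From the adipocyte, osteoblast and vitamin D target lists up to 10 genes with the largest absolute number of regions gained minus lost, summed over antibodies, could be named per comparison. From each antibody the 3 regions ranked first among gained and the 3 among lost could be named with their gene. Because the score is constant, the rank was the order of the deposited lists. In each of 84 lists tested, peaks early in the order were found more often in the other replicate, with a median of 99.9% for the first 10% of a list and 37.3% for the last 10%. Genes outside this rule in a comparison were chosen after their values were seen. These are Dcn and Sfrp1 at osteogenic day 7, Dcn, Sp7, Fabp4 and Vdr at day 15, Fabp4, Tsc22d3 and Fkbp5 in the adipogenic comparison with undifferentiated cells, Fabp4 and Pparg in that with osteogenic cells, and the genes whose VDR sites are counted.

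The mark coverage of genes was added after the region counts had been seen. For each mark the percent of a gene's window covered by regions was fitted in limma with a mean-variance trend, 4 libraries of each state with both treatments together, and two-sided moderated p-values were adjusted per mark and comparison. Genes with no coverage in any of the 8 libraries were not tested, and limma offsets the variance of genes without spread. An adjusted p quoted with a coverage is from limma. Counts of calls add up the 5 marks, so a gene can count up to 5 times.

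The procedure was checked on simulated data. In simulated libraries 300 of 300 gained, 200 of 200 lost and 500 of 500 shared regions were found, a planted log2 difference of 1.5 in peak number came back as 1.46 with an exact p of 0.00154, 9 of 200 random lists passed, and 100 of 100 elements were found on each strand. Every planted region stood in all libraries of its group, the planted noise was small, and that p is the smallest the test can give. These simulations therefore check the counting and not its power on the real replicates. For limma, simulated H3K4me1 coverage of undifferentiated libraries (4 against 4, 16607 genes) recovered 1 of 100 genes changed by 10 points and 20 of 100 changed by 25 points, with 2 false calls, so most changes of either size were missed in that comparison.

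The alternatives were a required overlap of 50% of the shorter region, 2 kb and 50 kb around genes, elements within 50 bp, covered length in place of peak number, vehicle libraries only, each replicate left out, the replicate number as a block, and lists of equal length or the first part of each list by order. For coverage they were equal covered length, 2 kb around genes, treatment as a covariate, the block, vehicle libraries only and each replicate left out. The software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, samtools 1.23.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.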

Results

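Chromatin immunoprecipitation with sequencing was done on mouse marrow-derived mesenchymal stem cells in 4 states: undifferentiated, 7 and 15 days in osteogenic medium, and 7 days in adipogenic medium. The antibodies were against the vitamin D receptor VDR, its dimer partner RXR, the osteoblast regulator RUNX2, the C/EBP factors CEBPB and CEBPA, the adipocyte regulator PPARG, and 5 histone marks. H4K5Ac and H3K9Ac are marks of active chromatin, H3K4me1 of enhancers, H3K4me3 of promoters and H3K36me3 of transcribed gene bodies. VDR, RXR and the marks were profiled after vehicle and after 100 nM 1,25(OH)2D3, the hormonal form of vitamin D, in 16 libraries each. RUNX2 and CEBPB were profiled in vehicle cells of the 4 states (8 libraries each), CEBPA and PPARG in vehicle cells of all states but osteogenic day 15 (6 libraries each). Every one of the 70 groups held 2 replicates, which gives 140 peak lists. Depth ran from 2463376 to 126432744 tags per library with a median of 38843448, and the lists held from 249 to 78749 peaks. H3K4me3 was sequenced to between 2463376 and 22972825 tags, VDR to between 20123975 and 126432744.

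The first question was what 1,25(OH)2D3 does to the binding of its receptor. 1,25(OH)2D3 raised the number of VDR peaks 3.46-fold over the 4 states (a log2 difference of 1.79). Undifferentiated cells held 4947 ± 273 VDR peaks (SD, n = 2) with vehicle and 18552 ± 2600 with the hormone. At Cyp24a1, which encodes the enzyme that breaks down 1,25(OH)2D3, undifferentiated cells held 0 VDR sites in both replicates with vehicle and 1 with hormone. Vdr itself went from 0 to 4 sites, Spp1, which encodes the bone matrix protein osteopontin, from 1 to 3, and the Wnt co-receptor gene Lrp5 from 1 to 4. The two-sided exact permutation test over 1296 labellings gave p = 0.0185. Without either replicate the log2 difference was 1.58 or 2.00, in a design then too small to reach the threshold.

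Of the 19 genes in the list of vitamin D targets, 3 had a VDR site in vehicle-treated undifferentiated cells and 10 with the hormone. Tnfsf11, the osteoclast differentiation factor RANKL, went from 0 sites to 1, the pyrophosphate-producing enzyme gene Enpp1 from 0 to 2, and the prostaglandin transporter gene Slco2a1 from 0 to 2. Cdkn1a, a cell-cycle inhibitor gene, held 1 site under both conditions. In osteogenic cells 1 target gene had a site with vehicle, against 2 with the hormone at day 7 and 5 at day 15. In adipogenic cells the counts were 1 and 2. Spp1 held 2 sites with the hormone in each differentiated state and 0 with vehicle. As background, 2024 of 22225 protein-coding genes had a VDR site in vehicle-treated and 5595 in hormone-treated undifferentiated cells. The osteoblast list went from 6 to 15 of 26 genes and the adipocyte list from 6 to 12 of 28, so the rise was not particular to the vitamin D targets. These gene counts carry no test.

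Counting a region as gained when both hormone-treated libraries and neither vehicle library held it, VDR gained 6819 regions and lost 86 in undifferentiated cells. It gained 481 and lost 0 at osteogenic day 7, gained 948 and lost 2 at day 15, and gained 246 and lost 3 in adipogenic cells. The gained regions ranked first included one upstream of Sec14l1 in undifferentiated cells (mm9 chromosome 11, 116949648 to 116950048), an intron of Mical2 at osteogenic day 7 (chromosome 7, 119410207 to 119410536) and a region upstream of Map3k7 at day 15 (chromosome 4, 32028614 to 32028940). In adipogenic cells they included an intron of Gmfb (chromosome 14, 47441020 to 47441404) and a region upstream of Prg2 (chromosome 2, 84801512 to 84801861). Of the 6819 regions gained in undifferentiated cells, 89.4% lay in H3K4me1 regions of vehicle-treated cells, against a mean of 12.1% after circular shifts. RXR sites of vehicle-treated cells covered 66.0% of them (0.663% after shifts), RUNX2 sites 56.5% (0.841%) and H3K4me3 regions 12.2% (1.45%). PPARG sites of the same cells covered 58.3%, CEBPA sites 51.6% and CEBPB sites 51.5%, so the overlap was not particular to RXR and RUNX2.

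**Figure D1:**
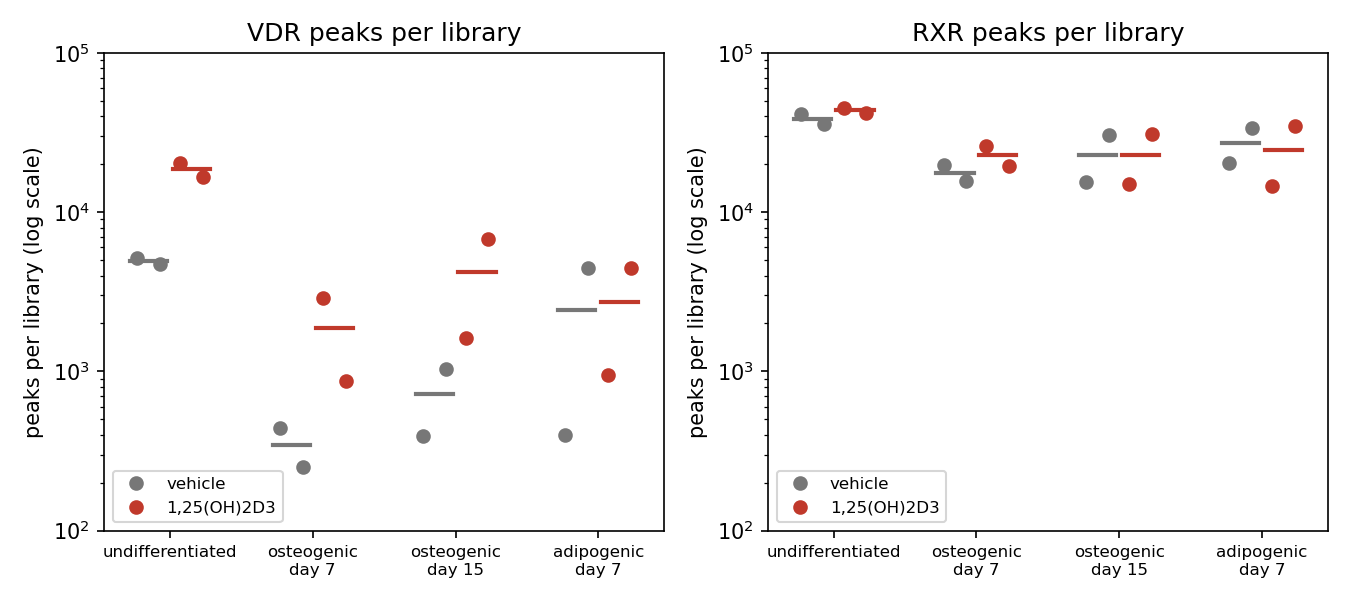
Number of VDR peaks and RXR peaks per library (log axis) in the 4 cell states with vehicle or 1,25(OH)2D3; points are libraries and lines are means of 2 replicates. VDR libraries ranged from 249 to 20390 peaks, RXR libraries from 14549 to 45239.

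For RXR, the partner with which VDR binds most of its elements, no change in peak number with the hormone was detected. Its peak number was 1.05-fold that of vehicle cells (log2 0.07, two-sided exact permutation p = 0.755), a difference that turned to -0.00494 without replicate 2. For the marks the ratio lay between 0.978 for H3K9Ac and 1.03 for H3K4me3. The exact permutation test passed the threshold for 0 of the 5 marks, all with an adjusted p of 0.991, and 0 had an unadjusted p under 0.05. The hormone effect on VDR was 3.73-fold in undifferentiated cells, 4.78-fold at osteogenic day 7, 5.21-fold at day 15 and 1.54-fold in adipogenic cells. In adipogenic cells the libraries that share a replicate number gave 2.38-fold and 0.997-fold. Whether the effect differed between states was tested by an exact permutation over all pairings of the states' effects, which gave p = 0.0762 for VDR and 0.0667 for RXR, both 0.267 after adjustment over 7 antibodies.

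The next question was how receptor binding differs once the cells have differentiated. Differentiated cells held fewer VDR peaks than undifferentiated cells. Over both treatments the count was 11749 ± 7998 (SD, n = 4) in undifferentiated cells, 1108 ± 1204 at osteogenic day 7, 2463 ± 2929 at day 15 and 2573 ± 2205 in adipogenic cells. RXR peaks numbered 41048 ± 3861, 20280 ± 4366, 22938 ± 8893 and 25914 ± 9993 in the same order. The log2 difference was -2.99 for VDR (0.126-fold, two-sided exact permutation p = 0.00128 over 784 labellings) and -0.90 for RXR (0.535-fold, exact permutation p = 0.00255). Without either replicate the differences were -3.64 or -2.33 for VDR and -1.25 or -0.56 for RXR, in a design then too small to reach the threshold. By covered length in place of peak number the RXR difference was -0.53 and did not pass. Of the other 9 antibodies, 0 passed the exact permutation test, 0 had an unadjusted p under 0.05, and the lowest p was 0.0561 for H4K5Ac. Even so, the peak number of the other factors was lower in differentiated cells, 0.641-fold for RUNX2, 0.593-fold for CEBPB, 0.621-fold for PPARG and 0.842-fold for CEBPA. The marks lay between 0.807-fold for H3K36me3 and 1.07-fold for H4K5Ac. RUNX2 and CEBPB have only 28 labellings, which limits their tests. For CEBPA and PPARG the smallest p that 6 libraries allow is 0.0667. A loss particular to VDR and RXR therefore cannot be read from these tests.

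Of 10618 VDR regions held by both hormone-treated replicates of undifferentiated cells, 7.05% (exact 95% interval 6.57% to 7.56%) were held by both replicates at osteogenic day 7. At day 15 the share was 11.7% (11.1% to 12.3%) and in adipogenic cells 5.36% (4.94% to 5.80%). With VDR lists of equal length the shares were 62.1%, 65.8% and 38.7%. With 1 differentiated replicate in place of both, osteogenic day 7 gave 4.86% or 12.6%, day 15 gave 7.01% or 34.6%, and adipogenic cells gave 4.13% or 13.6%. All 16 VDR libraries held 223 regions in common, and 98.7% of these lay in H3K4me3 regions of undifferentiated cells.

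Replicates shared more regions than libraries of different states for 8 of the 11 antibodies in exact permutation tests over pairings of vehicle libraries. The share was 86.4% between replicates and 84.0% between states for H3K4me3, and 58.1% and 35.5% for CEBPB. VDR gave 29.0% and 22.1% (p = 0.210, exact permutation), and CEBPA and PPARG sat at the smallest p that 15 pairings give, 0.0667. Regions held by all libraries of 1 state and by none of another numbered 216449 over the 11 antibodies. They were 47757 for CEBPB, 42578 for CEBPA, 25029 for RUNX2, 19275 for H3K4me1, 1024 for VDR and 631 for H3K4me3. CEBPB, CEBPA, RUNX2 and PPARG had 2 libraries per state and the other antibodies 4. Fewer libraries make the criterion easier, so these counts cannot be ranked across the antibodies. Lists of equal length lowered the total to 141422 and the first 50% of each list to 114833, and without replicate 1 or 2 it was 390804 or 381341.

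To ask which genes carry new marks as cells enter the bone lineage, each mark was scored as the percent of a gene body, with 10 kb on each side, that its regions cover. At osteogenic day 7, H3K36me3 covered 64.8% ± 2.30 (SD, n = 4) of Dcn, which encodes the collagen-binding proteoglycan decorin, against 1.39% ± 1.83 in undifferentiated cells (adjusted p = 0.000146). Relative to the median gene, that was a gain of 65.7 points. Bmp2, which encodes a bone morphogenetic protein, had 10.8% ± 0.970 of H3K4me3 and a listed 0% in undifferentiated cells (adjusted p = 2.09e-05). Ibsp, the bone sialoprotein gene, had 10.5% ± 1.67 of H3K9Ac, again against 0%. H3K36me3 was lower at Sfrp1, a secreted Wnt inhibitor gene, at 19.2% ± 22.4 against 72.6% ± 3.69, and at Vdr, at 20.6% ± 13.7 against 61.3% ± 10.8.

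Among osteoblast genes at osteogenic day 7, H3K9Ac was higher for 4 of 24 (7 adjusted over the list alone) and lower for 0. Besides Ibsp these included Alpl, the alkaline phosphatase of mineralisation, at 16.9% ± 2.53 against 1.94% ± 0.744 (adjusted p = 0.00109). With lists of equal covered length 0 of 22 osteoblast genes passed in limma and 5 had an unadjusted p under 0.05, and the adjusted p for Bmp2 H3K4me3 was 0.365 and for Alpl H3K9Ac 0.568. Dcn (7.67e-05), Sfrp1 (0.00557) and Vdr (0.00679) passed there. Of the adipocyte genes, 8 of 23 had lower H3K36me3 (12 adjusted over the list alone), and 5 of 21 with equal covered length. At Lpl, the lipoprotein lipase gene, it was 55.3% ± 9.55 against 74.5% ± 4.25 (adjusted p = 0.0483). Of the vitamin D target genes, 4 of 16 had lower H3K36me3 (5 adjusted over the list alone), and with equal covered length 2 lower, Vdr among them, and 1 higher. Housekeeping genes had 1 of 12 lower. A few genes of other lists were called too, with no test of coverage over a list as a whole. H3K9Ac was higher for 3 of 18 Wnt and TGF-beta signalling genes (5 adjusted over the list alone), 1 of 16 mesenchymal progenitor genes (5 adjusted over the list alone) and 1 of 7 endothelial markers (1 adjusted over the list alone). Under equal covered length limma called 0 of each (5, 1 and 0 with an unadjusted p under 0.05). H3K36me3 was lower for 5 of 17 Wnt and TGF-beta signalling genes (7 adjusted over the list alone), and for 5 of 16 under equal covered length.

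Counted over all protein-coding genes at osteogenic day 7, 855 gene and mark pairs were higher and 1394 lower, which equal covered length turned to 1602 and 1449. The share of calls that were higher was 76.6% for H4K5Ac, 91.6% for H3K9Ac, 22.1% for H3K4me1, 25.5% for H3K4me3 and 22.1% for H3K36me3. With equal covered length these became 46.3%, 63.7%, 60.4%, 80.2% and 44.0%, on the other side of 50% for 3 of the 5 marks. The median gene moved by 1.08, 0.267, -1.69, -0.573 and -2.30 points in the same order of marks. The 2249 calls became 1236 with treatment as a covariate and 5832 without replicate 2, of which 4897 were H3K4me1 calls (4.55% higher). Leaving out replicate 1 or 2 gave 192 or 173 calls in place of 370 for H3K9Ac, and 1711 or 638 in place of 1358 for H3K36me3. The higher share without replicate 1 was 48.6% for H3K4me3 and 43.0% for H3K36me3. Without replicate 1 limma made 0 calls for H4K5Ac and H3K4me1 (3224 and 3046 with an unadjusted p under 0.05), and without replicate 2 it made 0 for H4K5Ac (3020 unadjusted). With vehicle libraries alone limma made 0 calls, with 5603 at an unadjusted p under 0.05.

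Over the whole genome, more regions of CEBPB, PPARG and RUNX2 were lost than gained at osteogenic day 7, where lost means held by every undifferentiated and no osteogenic library. CEBPB lost 20351 regions and gained 188, PPARG lost 11502 and gained 1377, and RUNX2 lost 7274 and gained 2643. The undifferentiated lists were longer, with a mean of 61137 peaks against 25411 for CEBPB, 34741.5 against 16975.5 for PPARG and 51784.5 against 36766.5 for RUNX2. Longer lists favour loss, and equal-length counts are not given here, a limit shared by the net counts per gene below. Runx2, which encodes the master regulator of osteoblasts (chromosome 17, 44632936 to 44951746), gained 11 regions over all antibodies and lost 25, with 5 more RUNX2 regions gained than lost and a CEBPB net of -13. Zfp423, a preadipocyte commitment factor gene (chromosome 8, 90185709 to 90483494), gained 1 and lost 16, and Pparg (chromosome 6, 115311239 to 115440419) gained 3 and lost 12. Ibsp (chromosome 5, 104728190 to 104740488) gained 5 and lost 0. Summed over all antibodies, marks included, net loss was seen at 24 of 28 adipocyte, 18 of 26 osteoblast, 14 of 19 vitamin D target and 12 of 12 housekeeping genes. Against genes matched for the number of nearby regions, osteoblast genes had more RUNX2 regions gained minus lost, 0.269 per gene against -0.368 (7 genes net gained and 5 net lost, adjusted p = 0.0465). Runx2 alone, with its net of 5 RUNX2 regions, weighs heavily in this mean over 26 genes. Lists of equal length ended this call, and with 2 kb around the gene 0 osteoblast calls passed. The gained regions ranked first included an H3K4me3 region in an intron of Bmp2 (chromosome 2, 133377429 to 133382013), one in an intron of Tnfrsf19 (chromosome 14, 61661579 to 61666010) and a RUNX2 region in an intron of Runx1 (chromosome 16, 92782755 to 92783053).

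By day 15 of osteogenic medium Bmp2, Ibsp and Sp7 had more H3K9Ac than in undifferentiated cells. Bmp2 H3K9Ac covered 22.5% ± 2.79 (SD, n = 4) against a listed 0% in undifferentiated cells (adjusted p = 0.000163), and its H3K36me3 covered 23.2% ± 2.91 against 0%. Ibsp H3K9Ac covered 18.4% ± 5.28 against 0% (adjusted p = 0.00365). H3K9Ac of Sp7, the osteoblast transcription factor osterix, was 76.3% ± 1.33 against 39.6% ± 17.7 (adjusted p = 0.0344). At Dcn H3K36me3 reached 77.9% ± 2.50. On the adipocyte side, H3K4me1 of Lpl was 20.4% ± 2.33 against 76.8% ± 7.94 and that of Pparg 45.4% ± 9.50 against 91.2% ± 4.05 (adjusted p = 0.00046 and 0.00176).

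Osteoblast genes had higher H3K9Ac for 6 of 24 (11 adjusted over the list alone) and higher H4K5Ac for 6 of 24 (6 adjusted over the list alone), with 0 lower. With lists of equal covered length these were 3 of 22 and 1 of 21, and Bmp2, Ibsp and Sp7 passed there for H3K9Ac (adjusted p = 0.000148, 0.000805 and 0.00853). Without replicate 2 limma made 0 calls over all genes for either mark, with 4214 at an unadjusted p under 0.05 for H4K5Ac and 2431 for H3K9Ac. Over all genes H4K5Ac was higher for 2305 of 16210. It was higher for 4 of 16 mesenchymal progenitor genes and lower for 1 (5 and 2 adjusted over the list alone), and higher for 2 of 7 endothelial (2 adjusted over the list alone), 1 of 9 chondrocyte (2 adjusted over the list alone), 1 of 8 muscle and 1 of 8 haematopoietic markers (1 each adjusted over the list alone). Of the muscle markers 1 was lower. Under equal covered length 2 of 15 progenitor genes were higher and 1 lower, 1 of 8 chondrocyte markers higher and 1 lower, and limma called 0 of 5 endothelial, 0 of 2 muscle and 0 of 4 haematopoietic markers (1, 2 and 3 with an unadjusted p under 0.05). H3K9Ac was higher for 3 of 18 Wnt and TGF-beta signalling genes and lower for 2 (5 and 3 adjusted over the list alone), 4 and 2 of 17 under equal covered length, and for 1 of 8 endothelial markers (1 adjusted over the list alone), 1 of 3 under equal covered length. Adipocyte genes had lower H3K4me1 for 12 of 27 (18 adjusted over the list alone), lower H3K36me3 for 12 of 23 (16 adjusted over the list alone) and lower H3K4me3 for 10 of 20 (13 adjusted over the list alone). Of these lists 10, 6 and 4 genes were lower with equal covered length, and 0 were higher. H3K36me3 was lower for 6 of 17 Wnt and TGF-beta signalling genes and higher for 1 (7 and 1 adjusted over the list alone), and lower for 5 of 13 mesenchymal progenitor genes (5 adjusted over the list alone), with 6 and 2 lower under equal covered length. Fabp4, the fatty acid carrier of adipocytes, had 22.7% ± 8.11 of H3K4me1 against 52.1% ± 8.45 (adjusted p = 0.0138). Among vitamin D targets H3K36me3 was lower for 5 of 17 and higher for 1 (6 and 2 adjusted over the list alone), and with equal covered length lower for 4 and higher for 2. It stood at 2.88% ± 2.50 against 72.9% ± 4.80 for Slco2a1 and at 17.4% ± 3.24 against 61.3% ± 10.8 for Vdr. Housekeeping genes had lower H3K4me3 for 4 of 12 (7 adjusted over the list alone), and with equal covered length 2 lower and 1 higher. Over all genes H3K4me3 was lower for 3746 of 13478 and higher for 66. With equal covered length 449 were lower and 592 higher. H3K4me3 regions covered 24.1 ± 3.91 Mb (SD, n = 4) at day 15 against 32.9 ± 4.01 Mb in undifferentiated cells. The lowest depth of all libraries, 2463376 tags, was that of a day 15 H3K4me3 library. The H3K4me3 losses of both lists thus came with a general drop, whose link to depth was not tested.

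Over all genes at day 15, 4511 calls were higher and 7938 lower, which equal covered length turned to 5584 and 4029. Higher calls made up 77.8% for H4K5Ac, 74.2% for H3K9Ac, 18.5% for H3K4me1, 1.73% for H3K4me3 and 36.3% for H3K36me3. With equal covered length they made up 51.9%, 62.3%, 72.4%, 56.9% and 46.0%. The median gene moved by 2.13, 0.0995, -1.56, -1.62 and -1.44 points. Without replicate 1 the 12449 calls became 6444, with 0 in limma for H3K4me1 (2663 with an unadjusted p under 0.05), 149 in place of 3812 for H3K4me3 (34.9% higher) and 1806 in place of 3535 for H3K36me3 (61.5% higher). Without replicate 2 H3K4me1 gave 5972 in place of 1313 (7.12% higher) and H3K4me3 6551 (0.580% higher). Vehicle libraries alone gave 195.

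Regions gained at day 15 included an H3K36me3 region over Lama4, a laminin chain gene (chromosome 10, 38759050 to 38819751), and an H3K9Ac region upstream of the cytokine gene Il33 (chromosome 19, 29991770 to 30006067). H3K36me3 covered 72.6% ± 4.70 (SD, n = 4) of Lama4 against 1.16% ± 0.464 in undifferentiated cells (adjusted p = 2.68e-05). Bmp2 (chromosome 2, 133377895 to 133388621) gained 4 regions and lost 0. Over the whole genome CEBPB gained 8976 regions and lost 15667, RUNX2 gained 962 and lost 6408, and RXR gained 91 and lost 3034. The undifferentiated lists of these factors were on average longer here too, which favours loss. For RUNX2 the gained and lost regions came to 7370, against 7093 in the highest other split of the same libraries. Only 3 splits exist there, too few for a test, so this RUNX2 count hardly exceeds a mixed grouping. Over all antibodies net loss was seen at 17 of 28 adipocyte genes, 11 of 26 osteoblast genes, 10 of 19 vitamin D targets and 7 of 12 housekeeping genes. Osteoblast genes again had more RUNX2 regions gained minus lost than matched genes, 0.115 against -0.428 per gene (adjusted p = 0.0321). Runx2 alone had 3 more RUNX2 regions gained than lost, which weighs heavily in this mean over 26 genes. A gain of RUNX2 regions across the list cannot be read from it. This call too ended with lists of equal length and with 2 kb around the gene.

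Adipogenic cells were then compared with undifferentiated cells. H3K36me3 covered 93.9% ± 0.676 (SD, n = 4) of Zbtb16, a zinc-finger factor gene known to respond to glucocorticoids, against a listed 0% (adjusted p = 3.77e-07). It covered 46.8% ± 1.16 of Cd36, the fatty acid translocase gene, against 0%. H3K4me1 of Plin1, the lipid droplet coat protein perilipin, was 90.6% ± 0.548 against 21.2% ± 3.33, and H3K4me3 of Adipoq, the hormone adiponectin, 17.4% ± 2.70 against 0% (adjusted p = 2.05e-06 and 7.34e-05). H3K36me3 of Sfrp1 fell from 72.6% ± 3.69 to 0%, and that of Spp1 from 54.3% ± 19.0 to 21.2% ± 4.04 (adjusted p = 5.44e-07 and 0.0172). Relative to the median gene, H3K36me3 differed by 90.3 points at Zbtb16, 43.2 at Cd36 and -76.2 at Sfrp1.

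H4K5Ac was higher for 28 of 28 adipocyte genes (28 adjusted over the list alone), H3K4me1 for 23 of 28 (26 adjusted over the list alone) and H3K9Ac for 21 of 26 (23 adjusted over the list alone), with 0 lower for each. The counts were 24 of 26, 18 of 26 and 23 of 26 with equal covered length. Over all genes, at the deposited region lengths, H4K5Ac was higher for 8638 of 16729, H3K4me1 for 7771 of 17543 and H3K9Ac for 1112 of 15794. H3K9Ac at Fabp4 was 76.8% ± 1.36 against 18.2% ± 7.09, and at Lpl 77.5% ± 2.93 against 28.0% ± 6.79 (adjusted p = 0.000112 and 0.000263). Lpl nonetheless lost 7 more regions than it gained. Osteoblast genes went both ways, with H4K5Ac higher for 8 of 23 and lower for 2 (8 and 1 adjusted over the list alone), and 4 higher and 5 lower with equal covered length. Alpl, on that list, had 77.4% ± 8.47 of H4K5Ac against 10.3% ± 6.82. Among vitamin D targets H3K36me3 was higher for 6 of 17 and lower for 5 (6 and 6 adjusted over the list alone), and with equal covered length 5 and 4. Of housekeeping genes 10 of 12 had higher H4K5Ac, and 4 of 12 with equal covered length. Muscle markers had higher H4K5Ac for 6 of 8 (6 adjusted over the list alone) and higher H3K4me1 for 6 of 9 (6 adjusted over the list alone), and haematopoietic markers higher H3K4me1 for 6 of 10 (6 adjusted over the list alone). Under equal covered length limma called 0 of 4 higher and 1 lower (2 with an unadjusted p under 0.05), 1 of 7 higher, and 1 of 4 higher and 1 lower.

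Glucocorticoid response genes carried more H4K5Ac in adipogenic cells, whose medium held dexamethasone, for 10 of 11 genes (10 adjusted over the list alone) and under equal covered length too. Over all genes H4K5Ac was higher for 8638 of 16729, and a link of the list count to dexamethasone was not tested. H3K36me3 at Tsc22d3, a glucocorticoid-induced leucine zipper gene, was 74.1% ± 4.95 (SD, n = 4) against 2.89% ± 1.40, and H4K5Ac at Fkbp5, which encodes a chaperone partner of the glucocorticoid receptor, was 99.3% ± 0.762 against 50.1% ± 6.15 (adjusted p = 1.37e-06 and 7.9e-06). As a list these genes went both ways in H3K36me3, with 3 of 11 higher and 2 lower (3 and 2 adjusted over the list alone), 3 and 1 of 9 under equal covered length. Against matched genes this list had more H3K9Ac regions gained minus lost, 0.909 per gene (adjusted p = 0.0168), a call that lists of equal length end.

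In regions, Cd36 (chromosome 5, 17287508 to 17394777) gained 37 and lost 1 against undifferentiated cells. Runx2 gained 8 and lost 43, Vdr (chromosome 15, 97684856 to 97741061) gained 0 and lost 7, and Alpl gained 12 and lost 0. Over all antibodies adipocyte genes showed a net gain at 16 of 28 and a net loss at 9. Osteoblast genes showed a net loss at 18 of 26, vitamin D targets at 11 of 19 and housekeeping genes at 6 of 12. The gained regions ranked first included H3K4me3 in a coding exon of Zbtb16 (chromosome 9, 48636459 to 48645484) and in an intron of Adipoq (chromosome 16, 23145141 to 23151334), and a PPARG region in an untranslated region of Cd36 (chromosome 5, 17341441 to 17341845). An H3K36me3 region in an intron of Sfrp1 was lost (chromosome 8, 24523235 to 24562341).

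Higher calls numbered 22954 and lower calls 3635. They were higher in 93.1% of cases for H4K5Ac, 64.4% for H3K9Ac, 92.7% for H3K4me1, 44.4% for H3K4me3 and 77.7% for H3K36me3, and with equal covered length in 58.1%, 66.7%, 66.4%, 49.5% and 63.3%. The median gene moved by 7.90, 0.0827, 6.94, -0.198 and 3.65 points. Equal covered length lowered the 26589 calls to 16522, of which 10356 were higher and 6166 lower. Without replicate 1 H3K9Ac gave 838 calls in place of 1727 and H3K4me3 137 in place of 480, and without replicate 2 H3K9Ac gave 2851. Vehicle libraries alone gave 11403, with 0 in limma for H3K9Ac (2306 with an unadjusted p under 0.05).

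The most direct comparison of lineages set adipogenic against osteogenic cells at day 7. H3K4me1 of Plin1 was 90.6% ± 0.548 (SD, n = 4) in adipogenic and 9.01% ± 5.83 in osteogenic cells, and that of Lipe, the hormone-sensitive lipase gene, 77.2% ± 1.09 and 14.2% ± 1.35 (adjusted p = 1.35e-07 and 6.14e-08). H3K36me3 covered 83.1% ± 0.473 of the cholesterol transporter gene Abcg1 in adipogenic cells and a listed 0% in osteogenic cells. In the other direction Dcn H3K36me3 was 0% against 64.8% ± 2.30, and H4K5Ac of Cdh11, the cadherin of osteoblasts, 10.6% ± 3.22 against 75.1% ± 10.6 (adjusted p = 1.23e-07 and 2.73e-05). Runx2 had less H3K9Ac in adipogenic cells, 24.7% ± 9.78 against 43.3% ± 4.14, and so did Spp1, 31.6% ± 9.33 against 57.0% ± 10.2 (adjusted p = 0.0314 and 0.0248). Relative to the median gene the difference was 72.2 points at Plin1 and -72.2 at Dcn.

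All 28 adipocyte genes had higher H3K4me1 in adipogenic cells (28 adjusted over the list alone), 26 of 28 higher H4K5Ac (27 adjusted over the list alone) and 22 of 27 higher H3K9Ac (24 adjusted over the list alone). With equal covered length these were 23, 22 and 24 of 26. Over all genes, at the deposited region lengths, H3K4me1 was higher for 11080 of 17569, H4K5Ac for 6932 of 16820 and H3K9Ac for 1341 of 15892. Fabp4 H3K9Ac was 76.8% ± 1.36 against 12.5% ± 14.4, and Pparg H3K9Ac 66.0% ± 18.3 against 19.2% ± 8.42 (adjusted p = 0.00044 and 0.0079). Osteoblast genes had lower H3K9Ac for 10 of 24 and higher for 1 (11 and 1 adjusted over the list alone), and with equal covered length for 6 and 1 of 22. In the same comparison H3K9Ac was lower for 3 of 6 endothelial markers (3 adjusted over the list alone), 6 of 16 mesenchymal progenitor genes (9 adjusted over the list alone, 1 higher in both) and 4 of 18 Wnt and TGF-beta signalling genes (9 adjusted over the list alone). Under equal covered length 3 progenitor genes were lower and 1 higher, 4 Wnt and TGF-beta signalling genes were lower, and limma called 0 of 4 endothelial markers (0 with an unadjusted p under 0.05). Sfrp4, a Wnt-binding protein gene, had 13.3% ± 2.73 of H3K9Ac against 60.2% ± 16.8, while Alpl had more H4K5Ac in adipogenic cells, 77.4% ± 8.47 against 21.0% ± 5.15. Glucocorticoid response genes had higher H4K5Ac for 9 of 11 (9 adjusted over the list alone) and 8 with equal covered length. Vitamin D targets had higher H3K36me3 for 9 of 16 and lower for 2 (9 and 2 adjusted over the list alone), and 5 and 3 of 15 with equal covered length. Housekeeping genes had higher H4K5Ac for 9 of 12 (10 adjusted over the list alone) and higher H3K4me1 for 9 of 12 (9 adjusted over the list alone). With equal covered length 4 were higher in H4K5Ac, and H3K4me1 split into 3 higher and 3 lower. Muscle markers had higher H3K4me1 for 8 of 9 (8 adjusted over the list alone) and higher H4K5Ac for 6 of 8 (7 adjusted over the list alone), and 3 of 7 and 1 of 7 under equal covered length. Haematopoietic markers had higher H3K4me1 for 6 of 10 (6 adjusted over the list alone), and under equal covered length 1 of 3 higher and 2 lower.

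**Figure D2:**
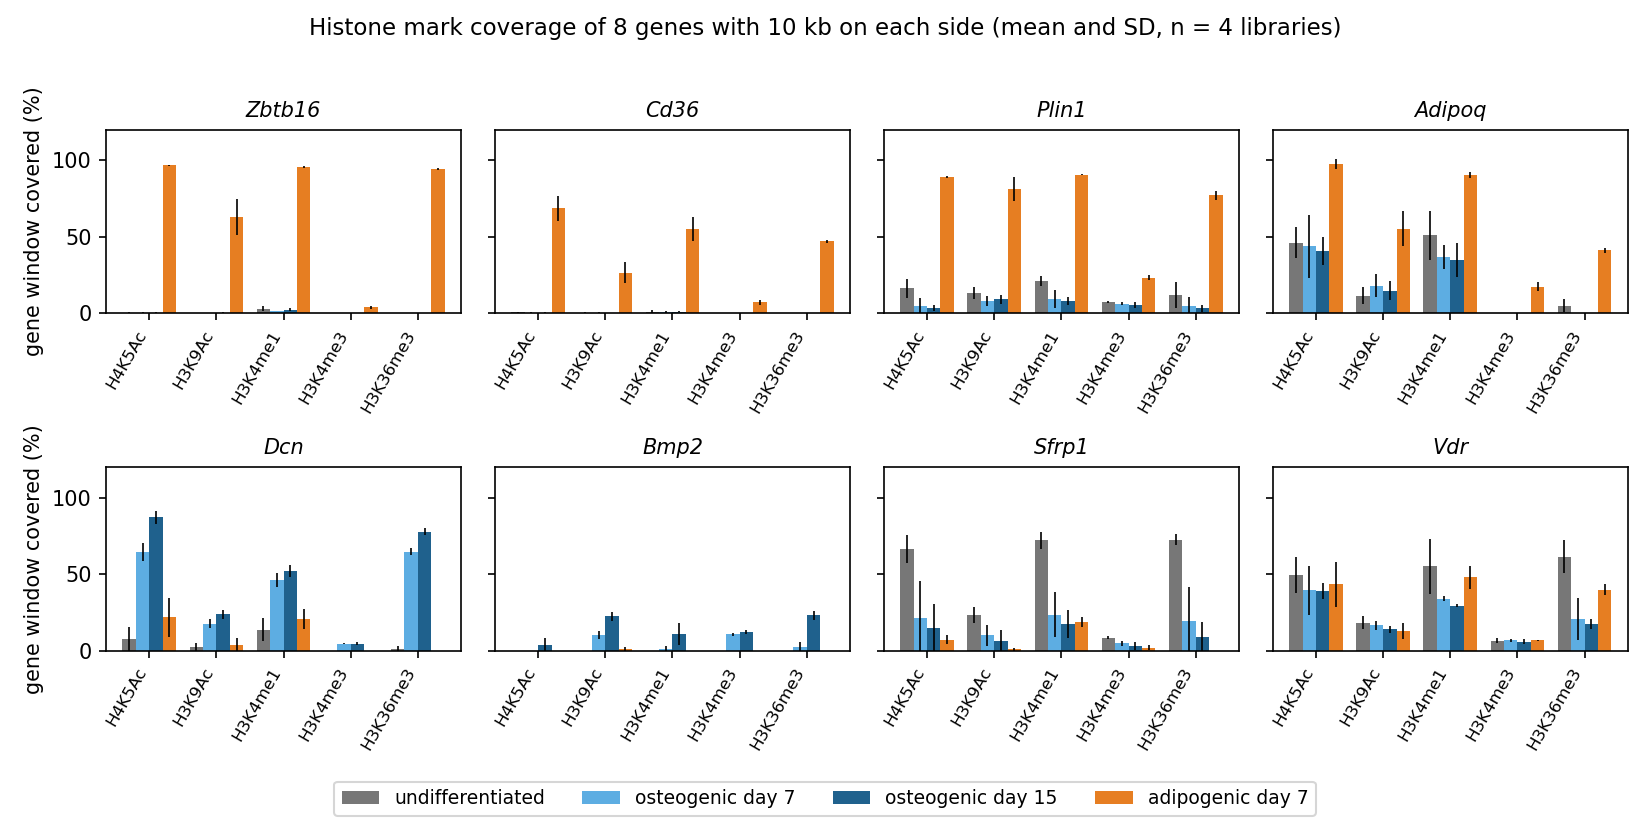
Percent of the gene window covered by each of the 5 marks (vertical axes) in the 4 cell states for Zbtb16, Cd36, Plin1, Adipoq, Dcn, Bmp2, Sfrp1 and Vdr; bars are means of 4 libraries and error bars are SD. H3K36me3 at Zbtb16 stood at 93.9% in adipogenic cells and 0% in undifferentiated cells, and at Dcn at 64.8% in osteogenic cells at day 7 and 0% in adipogenic cells.

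Of the region calls that told the day 7 lineages apart, 84.3% were adipogenic for H3K4me1, with an SD of 4.28 between replicates, 80.5% for CEBPB (SD 18.6) and 70.8% for PPARG (SD 0.214). For RUNX2 the adipogenic share was 17.4% (SD 19.7) and for H3K9Ac 31.9% (SD 5.95). Each SD is that of the shares from replicate 1 alone and replicate 2 alone, so it does not measure the spread of the share beside it. Single replicates gave 78.1% and 72.1% for H3K4me1 and 67.1% and 67.4% for PPARG, all below the shares above. For RUNX2 they gave 49.7% and 21.9%, both higher. The share was above 50% for 7 of 11 antibodies, VDR among them on only 25 regions (19 and 6), and for 3 of 11 without replicate 2. Equal list lengths turned it for RXR (48.4%), CEBPB (49.1%), H3K9Ac (54.8%), H3K4me3 (58.7%) and H3K36me3 (75.4%). Without replicate 2 it turned for VDR, RXR, CEBPA and H4K5Ac, and it moved to 49.7% for RUNX2 and 25.9% for H3K36me3, from 39.2%.

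**Figure D3:**
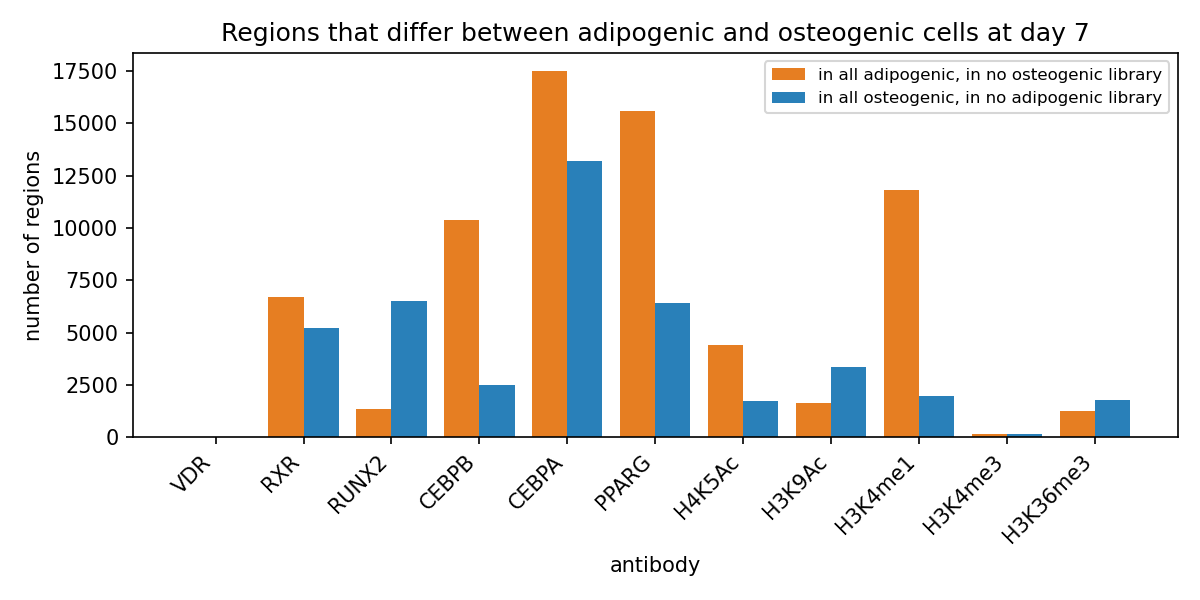
Number of regions (vertical axis) held by all adipogenic and no osteogenic day 7 libraries, and the reverse, for each antibody; bars are counts with no error. PPARG had 15599 adipogenic and 6426 osteogenic regions, RUNX2 1359 and 6512.

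Between the day 7 lineages Cd36 gained 36 regions in adipogenic cells and lost 0, and Zfp423 and Ebf2, both factors of the adipocyte lineage, had a net of 31 and 22. Tnfsf11 had a net of -12, Runx2 of -9 and Vdr of -5. Over all antibodies adipocyte genes showed a net gain at 24 of 28 and osteoblast genes a net loss at 17 of 26, while 7 of 12 housekeeping genes showed a net gain. PPARG and RXR regions overlapped in the intron of Lipe (PPARG at chromosome 7, 26176926 to 26177266; RXR at 26176923 to 26177292). Slc16a10, an amino acid transporter gene, held overlapping CEBPA and PPARG regions gained in an intron (chromosome 10, CEBPA at 39797446 to 39797775 and PPARG at 39797372 to 39797744). Lost regions included a RUNX2 region in an intron of Wnt7b (chromosome 15, 85404942 to 85405273), H4K5Ac in an intron of Cdh11 (chromosome 8, 105150891 to 105190002) and H3K36me3 in an intron of the retinoic acid synthesis gene Aldh1a2 (chromosome 9, 71064211 to 71146145).

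Counted over all genes, adipogenic cells had 28098 higher and 4388 lower calls against osteogenic cells. Higher calls made up 88.2% for H4K5Ac, 46.5% for H3K9Ac, 93.2% for H3K4me1, 69.4% for H3K4me3 and 90.6% for H3K36me3, and with equal covered length 71.0%, 66.1%, 51.6%, 47.0% and 73.9%. The median gene moved by 6.03, -0.259, 9.32, 0.289 and 7.37 points. Equal covered length lowered the 32486 calls to 20317, of which 12668 were higher and 7649 lower. Vehicle libraries alone gave 15897, with 0 in limma for H3K9Ac (2053 with an unadjusted p under 0.05) and 91 for H3K4me3, of which 38.5% were higher. Without replicate 2 the share of higher H3K9Ac calls was 58.3% (4883 calls in place of 2885), and without replicate 1 that of H3K4me3 was 46.3% (218 in place of 806).

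Gene lists were also compared with random genes matched for the number of regions near them, by regions gained minus lost per gene. Of 504 tests 16 passed, 15 of them above the matched genes. The adipocyte list passed in 9 of 42, all above: CEBPB between the day 7 lineages gave 1.43 against 0.556 (adjusted p = 0.0168), CEBPA against undifferentiated cells 1.29 against -0.0412 (adjusted p = 0.0224), and RXR against undifferentiated cells 0.464 against -0.340 (adjusted p = 0.0168). The osteoblast list passed in 3 of 42. Besides the RUNX2 results these were CEBPB regions in adipogenic against undifferentiated cells, -1.46 against -0.630 (adjusted p = 0.0472). The glucocorticoid list passed in 3 of 42, with RXR between the day 7 lineages at 1.55 against 0.314 (adjusted p = 0.0470), and the mesenchymal progenitor list in 1 of 42. The vitamin D target list passed in 0 of 42 (4 with an unadjusted p under 0.05 from the random lists), Wnt and TGF-beta signalling in 0 (1 unadjusted) and housekeeping in 0 (0 unadjusted). Markers of other cell types passed in 0 of 42 each, with 2 unadjusted for chondrocytes, 7 for muscle, 2 for haematopoietic cells, 6 for endothelium and 0 for neurons. The smallest p the random lists can give is 0.0001. With lists of equal length 6 of the 16 calls were shared, all of them adipocyte calls, and with 2 kb around the gene 5.

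The overlap of sites was then counted for pairs of factors. Circular shifts take no account of where peaks of other factors cluster. An excess over them therefore does not show that the proteins bind together. In hormone-treated undifferentiated cells 90.9% of VDR sites (9599 of 10556, exact 95% interval 90.4% to 91.5%) lay in an RXR site, against a mean of 0.721% after circular shifts. The share was 69.3% at osteogenic day 7, 74.6% at day 15 and 48.0% in adipogenic cells, where it was 82.7% without replicate 1. In osteogenic cells the first 50% of each list gave lower shares at both days, listed with the other alternatives below. CEBPB sites lay in RUNX2 sites at 32.7% in undifferentiated cells, 31.8% at osteogenic day 7 and 33.1% at day 15, against 7.51% in adipogenic cells. Without replicate 1 the share was 50.2% at day 15 and 16.6% in adipogenic cells. RXR sites lay in PPARG sites at 82.3% in adipogenic cells, 55.9% at osteogenic day 7 and 70.3% in undifferentiated cells. Of the RXR regions gained in adipogenic over osteogenic cells at day 7, 72.6% lay in PPARG regions gained there (0.475% after shifts), and of the lost ones 52.9% lay in lost PPARG regions. Differences between states in these shares were not tested.

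Known elements were counted at the sites of each factor. DR3, the direct repeat bound by the VDR and RXR dimer, lay within 100 bp of the centre in 2.36% of hormone-treated VDR sites in undifferentiated cells (exact 95% interval 2.08% to 2.67%), against 0.0568% in the flanks. It lay in 6.93% of sites at osteogenic day 7, 6.45% at day 15 and 9.11% in adipogenic cells. These sets held 822, 1364 and 615 sites, against 10556 in undifferentiated cells. Shares at equal list length are not given here, so a rise of DR3 with differentiation cannot be read from them. With vehicle the share was 1.14% in undifferentiated cells, 2 of 338 sites at osteogenic day 15, 0 of 244 at day 7 and 0 of 373 in adipogenic cells, and the upper exact limits of the 3 differentiated states are at most 2.12%. The RUNX element lay in 50.9%, 55.8%, 50.4% and 45.2% of RUNX2 sites in undifferentiated, osteogenic day 7, day 15 and adipogenic cells, with flanks between 14.8% and 15.0%. DR1, the repeat of PPARG and RXR, lay in 2.18% of PPARG sites in adipogenic cells and 0.754% at osteogenic day 7. It lay in 2.84% of RXR regions gained in adipogenic over osteogenic cells and in 0.116% of those lost, with 0.0867% in the flanks of the latter. The C/EBP element as planned, TTGCNNCAA, lay in 2.49% to 3.38% of CEBPB sites. Its spacing differs from that of the palindrome TTGCGCAA counted later, so these shares are no count of that palindrome. In 22 of 22 sets of factor sites the lower exact limit lay above the flanks, but the size of the excess for this element is not given here.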

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

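The permutation tests over cell states quoted in this part were chosen after the peak numbers had been seen. For H3K4me1 at osteogenic day 15, the share of tags in peaks of the hormone-treated replicate 1 was 27.5%, apart from the other 3 libraries at 31.9% to 32.3%. It was the 1 set of the 56 sets of 4 libraries tested to stand out in this way, where chance picks about 1 in 20.

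For 3 marks every library of 1 state had more peaks with 1,25(OH)2D3 than the vehicle library of the same replicate number, and every library of another had fewer. For H4K5Ac osteogenic day 7 exceeded day 15 by 0.12 in log2 peak number (exact permutation p over the 4 states 0.562). For H3K9Ac adipogenic cells exceeded osteogenic day 15 by 0.22 (exact permutation p = 0.724), and for H3K4me1 osteogenic day 7 exceeded day 15 by 0.0928 (exact permutation p = 0.533). After adjustment each p was 0.844, so none of the 3 differences passed the test over states. The difference between the pair of states alone was not tested.

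Peaks on the mitochondrial chromosome, left out of every comparison, numbered 169. They appeared in all 80 mark libraries, with 160 peaks, and in 8 of the 60 factor libraries, with 9. The input samples, which would give their background, are not analysed here.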

How the results depend on the processing

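The tests on lists of equal length, on the first 50% of each list, with total tags as a covariate, with the palindromic C/EBP element and all alternatives for mark coverage were chosen after the data had been seen. Among 26 results that answer a comparison, 131 alternatives left 88 within their limits, moved 35, took 7 below the threshold and turned 1. Among 44 results of single antibodies or states, 146 alternatives left 70 within limits, moved 67 and turned 9. Alternatives that ranked peaks by score were not run, since the score is constant, and neither was a stricter score for peak number. Where no cause is named, the cause was not tested.

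Leaving out each replicate gave 1.58 to 2.00 for the VDR response to 1,25(OH)2D3, -0.00494 to 0.15 for RXR, -3.64 to -2.33 for VDR in differentiated cells and -1.25 to -0.56 for RXR, all short of the threshold (smallest exact permutation p 0.125 with the hormone and 0.0625 in differentiated cells). RXR by covered length was -0.53 (exact permutation p = 0.0867). Separating regions numbered 114833 in the first 50% of each list, 141422 with equal lengths and 381341 to 390804 without a replicate, since fewer libraries make the criterion easier. Antibodies with a majority of adipogenic regions numbered 3 to 7 without a replicate. Shares that turned were, with equal lengths, RXR 48.4%, CEBPB 49.1%, H3K9Ac 54.8%, H3K4me3 58.7% and H3K36me3 75.4%, and without a replicate, VDR (20.6% to 99.7%), RXR (39.3% to 75.8%), CEBPA (45.6% to 65.4%) and H4K5Ac (49.3% to 70.3%).

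VDR sites in RXR sites were 83.1% with equal lengths (undifferentiated), 43.5% and 60.3% in the first 50% of the lists (osteogenic day 7 and 15), and without a replicate 82.9% to 90.9%, 72.6% to 84.8%, 77.4% to 87.8% and 47.3% to 82.7% in undifferentiated, osteogenic day 7, day 15 and adipogenic cells. CEBPB in RUNX2 sites was 22.0% in the first 50% at day 7, and without a replicate 31.1% to 47.6%, 33.5% to 43.7%, 39.2% to 50.2% and 10.6% to 16.6%. VDR sites kept were 62.1%, 65.8% and 38.7% with equal lengths, and 4.86% to 12.6%, 7.01% to 34.6% and 4.13% to 13.6% without a replicate. List tests passed in 26 cases at 50 kb, 12 of them shared, and in 5 at 2 kb.

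Coverage calls at osteogenic day 7 were 1236 with treatment as a covariate, 5367 with the replicate block, 2045 to 5832 without a replicate and 0 with vehicle alone. At day 15 they were 6444 to 16736 without a replicate and 195 with vehicle alone. Adipogenic calls were 16522 (equal covered length) and 11403 (vehicle alone) against undifferentiated cells, and 20317 and 15897 against osteogenic cells. Vehicle alone has 2 libraries per state, which limits power. Samples share only a number. The correlation of residuals by number exceeded 0.1 in 24 of 28 comparisons (0.0713 to 0.565, median 0.20), and with number as a block 6 of 7 results kept their call or count, the exception being the coverage count at osteogenic day 7 (VDR response to the hormone, exact permutation p = 0.0156 within the block).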

Other observations

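The tests of depth, of equal loss, of Vdr transcription, of covered length and of the separating regions were chosen after the results had been seen, while both DR3 tests were set beforehand. Mark coverage was added after the region counts had been seen, and the splits of its calls were set before those calls were seen. At the deposited region lengths, 307 genes were higher in all 5 marks in adipogenic than in osteogenic cells at day 7 and 51 lower. Over undifferentiated cells the numbers were 128 and 24 for adipogenic cells, 1 and 0 for osteogenic day 7 and 10 and 32 for day 15. Between the day 7 lineages, CEBPB regions gained lay in gained CEBPA regions at 62.0% (0.474% after shifts) and in gained H3K4me1 regions at 24.0%. RUNX2 regions lost lay in lost H3K9Ac regions at 12.2% (0.562% after shifts). A palindromic C/EBP element lay in 0.788% to 2.11% of CEBPB sites, against at most 0.0143% in their flanks.

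The region ranked first among those lost at osteogenic day 7 lay downstream of Axin2 for VDR (chromosome 11, 108873003 to 108873380), RXR (108873012 to 108873383), RUNX2 (108872989 to 108873374) and PPARG (108873012 to 108873370) alike. A region downstream of Gm6020 was ranked first or second among those lost at osteogenic day 15 for VDR (chromosome 19, 61275524 to 61275810), RXR and RUNX2. Regions at Gm10800 and Gm10801 (chromosome 2) and Gm10717 (chromosome 9, 3015014 to 3038836) ranked first for CEBPB, CEBPA, H3K9Ac or H3K4me1. The regions at these genes and at Gm6020 recur across unrelated antibodies, and only mitochondrial peaks were filtered out. Whether they reflect binding or an artefact was not tested, so they are not read as gained or lost binding.

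RXR regions gained or lost with the hormone numbered 3642 in undifferentiated cells, 1702 at osteogenic day 7, 771 at day 15 and 564 in adipogenic cells. The highest of the other 2 splits of each 4 libraries gave 8456, 4543, 15546 and 12841. For VDR the numbers were 6905, 481, 950 and 249, against 1131, 64, 439 and 2439. Only 3 splits exist, too few for a test.

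A group of 223 VDR regions was held by all 16 libraries, vehicle included, and 98.7% of it lay in H3K4me3 regions. Direct contact with DR3 elements was argued against: 0 of 223 held one, with an upper exact 95% limit of 1.64%, below the 2.99% of regions gained with the hormone. The lower limit of 0 did not exceed the flanks, which is consistent with a background of the immunoprecipitation at open promoters, as a hypothesis. Contact through other elements or through partners stays open: vehicle sites of RXR held 86.5% of these regions, those of PPARG 79.8%, RUNX2 76.7%, CEBPA 30.9% and CEBPB 22.0%.

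Differentiated cells held fewer VDR peaks, by -2.99 on the log2 scale. Sequencing depth as the whole cause was argued against, since the difference adjusted for total tags was -2.66 (exact permutation p = 0.00255). So was an equal loss of every factor from the handling of differentiated cultures, since VDR fell by 2.08 relative to RXR (0.236-fold, exact permutation p = 0.00255), although a loss from handling that strikes weak binding harder is not excluded. Lower transcription of Vdr may contribute: H3K36me3 over Vdr was lower past the threshold in 3 of 3 differentiated states. With equal covered length it differed by -38.7, -45.2 and -32.1 points at osteogenic day 7, day 15 and in adipogenic cells, the last with an adjusted p of 0.0639. The mean share of tags in peaks for VDR was 3.40%, 0.560%, 1.19% and 1.41% in undifferentiated, osteogenic day 7, day 15 and adipogenic cells. For RXR it was 12.2%, 5.91%, 5.75% and 11.9%. A lower yield of the immunoprecipitation was not tested apart from lower binding.

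Adipogenic libraries had a higher share of tags in regions than the others for the 5 marks, for instance 67.0% ± 0.681 (SD, n = 4) against 34.0% ± 5.28 (n = 12) for H3K4me1 and 47.9% ± 8.29 against 37.1% ± 7.17 for H3K4me3 (exact permutation p = 0.00128 and 0.0332). A difference in depth was argued against, since 5 of 5 marks stayed higher past the threshold after adjustment for total tags. A larger covered length as the whole cause was argued against for H4K5Ac, H3K9Ac, H3K4me1 and H3K36me3, since 4 of these 4 marks had a higher share per covered Mb past the threshold (exact permutation p = 0.00128 each), and for H3K9Ac the covered length was 93.6 ± 25.3 Mb against 107 ± 17.4 Mb. For H3K4me3 it cannot be told apart, since its share per Mb missed the threshold (1.55% ± 0.275 against 1.30% ± 0.259, exact permutation p = 0.112). Broader chromatin changes in adipogenic cells and a difference in the preparation of these cultures stay open, and the design does not separate them. The file headers name this share the approximate efficiency of the immunoprecipitation. It therefore cannot tell the yield of that step from a change in chromatin, and the coverage gains of adipogenic cells carry the same limit.

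Other splits of the libraries into groups of the same sizes were counted for each model, and chance was argued against where 1 of the splits, the real one, gave as many. The splits are few and were not adjusted over the antibodies and comparisons, so chance is not excluded for any single one. For regions that separate the states, 1 of 100 splits did so for VDR (1024, highest other 712), RXR (20748 and 3957), RUNX2 (25029 and 24654), CEBPB (47757 and 41168), H4K5Ac (10718 and 2668), H3K9Ac (8302 and 2667), H3K4me1 (19275 and 4979), H3K4me3 (631 and 189) and H3K36me3 (6688 and 1388). With VDR lists of equal length only 3 regions separated the states. Between single states 26 of 28 contrasts of 4 against 4 libraries exceeded every other split. Chance was not argued against for the others, both of VDR: 2 of 35 splits gave as many as the 25 regions between the day 7 lineages (highest other 132), and 3 of 35 as many as the 336 between osteogenic day 15, where the region at Gm6020 ranked first, and undifferentiated cells (highest other 555). For CEBPA (42578, highest other 31394) and PPARG (33699 and 21635) the 15 splits are too few. For coverage calls 1 of 35 splits did so in each comparison, with 2249 against 1644 at osteogenic day 7, 12449 against 9 at day 15, 26589 against 212 for adipogenic over undifferentiated cells and 32486 against 57 for adipogenic over osteogenic cells. The split with 1644 calls exchanges the hormone-treated replicate 1 of undifferentiated cells with the vehicle replicate 2 of osteogenic cells at day 7.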
